A study of Homo sapiens with 21 samples.

How the data were processed

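RNA from 21 cultures of cells labelled HepG2 was selected with poly(dT) beads and reverse transcribed with SmartScribe, per the labels' protocols. The deposited table of gene counts holds whole numbers per gene and library with no normalization, and the deposited FPKM table holds the authors' values (fragments per kilobase of gene length, scaled by a library size). HISAT2, DESeq2 and the genome build GRCh38 are named, without a role, per the submitters' processing notes, and the counting tool, its use of strand and the annotation release are not given in the sources used here. The FPKM equal the counts divided by gene length and 1 constant per library to within a relative deviation of 1.07e-06, and that constant was 0.948 to 1.00 times the library's count total.

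Each library was assigned to its group from its label, 3 libraries for each of 7 doses. Total counts per library were 27984517 to 43704155, and 3 counts correspond to 0.0686 to 0.107 CPM, which covers counting error only. Mitochondrial transcripts took 5.61% to 6.63% of the counts. The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts: genes were kept by filterByExpr, scaled by TMM, and fitted in 1 quasi-likelihood model of all 21 libraries, with 14 residual degrees of freedom. Each dose was compared with 0 µM, an F-test was run over the 7 groups and over the 6 treated doses, and a linear trend over log10 dose was tested among treated libraries. P-values were adjusted by Benjamini-Hochberg over the 16196 genes, with a threshold of 0.05. CPM are TMM-scaled in the comparisons, and standard errors were derived from the fold change and its F statistic.

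Before the data were examined, 38 gene lists with 764 entries were fixed. The symbols in the files matched 733 entries, a table of newer symbols matched 29, and 2 were not matched. Lists with fewer than 5 measured genes were not tested, which left 33 and removed 5. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists and the 6 doses together, and again with the correlation estimated per list and with fry. For the trend over dose the adjustment was over the 33 lists.

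The genes named were chosen by a rule set before the data were examined. At each dose these were the 10 largest rises and 10 largest falls (12 of each at 100 µM) among called genes with a mean log2 CPM of at least 1 and all 3 treated libraries beyond all 3 controls. For the trend the 10 steepest of each direction were taken, for the 7 groups the 10 smallest p-values, and for each list discussed up to 4 members with the smallest p. A further 8 genes, CYP2A6, CYP1A1, CYP1A2, CYP3A4, CYP2E1, HMOX1, NQO1 and ALB, were always examined. Cell type genes are given from their lists as levels.

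The test of a dose against control and camera were tested on simulated data first, in simulated counts for the comparison of 100 µM with control over 16196 genes; the F-tests, the trend over dose, fry, the offsets and limma on FPKM were not simulated. Of 50 genes each changed by 0.322, 0.585, 1 and 2 on the log2 scale, edgeR recovered 64%, 92%, 100% and 100%, with 8 false calls among 15996 unchanged genes. The changed genes were taken only from those with a mean log2 CPM above 1, in a single draw with genes independent of each other. Alternatives were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, limma on log2(FPKM + 1), other filters on low counts, the replicate number as a block, fits of only the 6 libraries compared, a 2-fold threshold, each library left out in turn, and offsets for gene length and GC content. Figures were drawn with matplotlib 3.10.9.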

Results

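Gene expression was measured by RNA sequencing in cells labelled HepG2, a human line derived from a liver tumour, after 6 h in serum-free medium with coumarin. Coumarin is a plant-derived fragrance compound that the liver enzyme CYP2A6 hydroxylates in humans. The 21 libraries formed 7 groups of 3, an untreated control at 0 µM and coumarin at 0.001, 0.01, 0.1, 1, 10 and 100 µM, and the design text calls the 3 samples of each group biological replicates. Total gene counts ranged from 27984517 to 43704155 per library. Of 58735 genes in the table, 16196 had enough counts to be tested. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.89 to 14.1 over the 21 pairs), so none was taken as a library deposited again; this does not separate cultures from repeat libraries of a culture, and the libraries were kept as separate samples on the design text alone. The biological coefficient of variation common to the tested genes was 0.0436. The question put by the design was which genes change with coumarin dose.

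The libraries labelled HepG2 held almost no transcripts of hepatocytes, the main cell type of the liver. Of 24 hepatocyte genes fixed as a list, 7 had no read in any library, 19 had at most 21 reads summed over the 21 libraries, and 1, the transcription factor gene FOXA1, reached 1 CPM (counts scaled per library total; 12 ± 0.75 SD, n = 21). ALB, which encodes serum albumin, had 0 reads in all 21 libraries, and AFP, which encodes the fetal albumin-like protein, had 15. A count of 0 allows up to 0.107 CPM in the shallowest library, counting error only. The coumarin hydroxylase gene CYP2A6 had 9 reads in all, and CYP1A2, CYP3A4 and CYP2E1 had 1, 1 and 5; none of these was tested. Genes of other lists were abundant: KRT7, a keratin of biliary and other simple epithelia, stood at 1210 ± 64 CPM, COL3A1 at 936 ± 28, COL5A1 at 351 ± 13, TAGLN at 79.4 ± 4.1, COL1A1 at 60.8 ± 4.7 and PDGFRB at 30.4 ± 2.2 (SD, n = 21). Not all genes of those lists were present: COL1A2 had 1 read in all and EPCAM had 0. The values below are therefore those of the cells as sequenced, under the label HepG2.

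**Figure D1:**
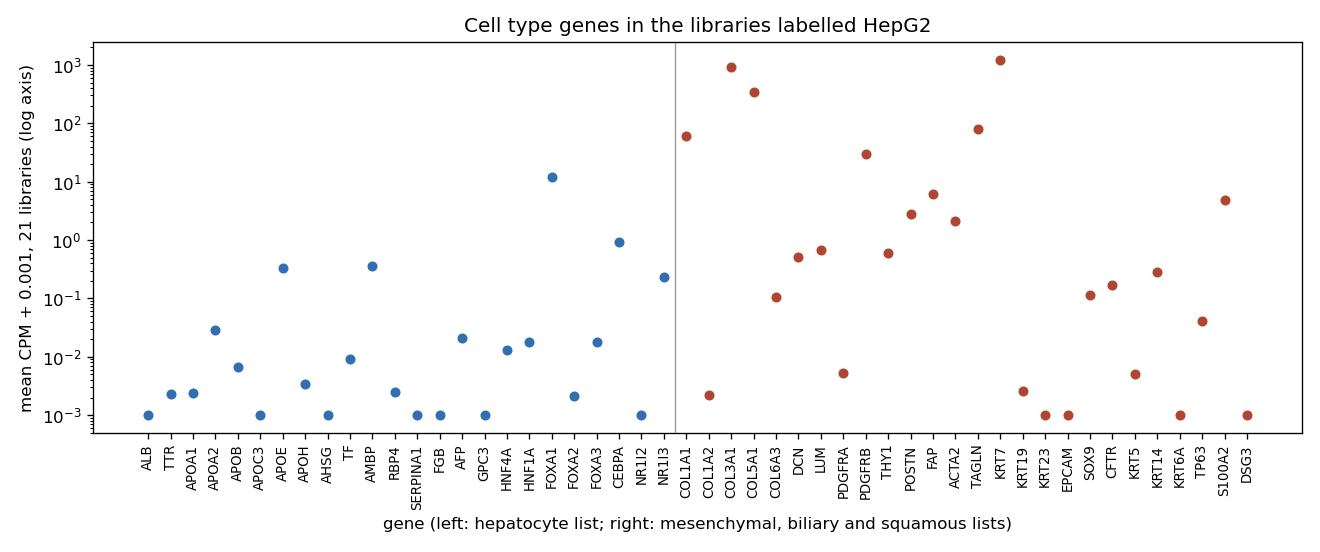
Mean CPM over the 21 libraries (log axis, with 0.001 added) for 24 hepatocyte genes in blue and for mesenchymal, biliary and squamous genes in red, 1 point per gene. FOXA1 is the hepatocyte gene above 1 CPM, at 12, while KRT7 stands at 1210 and COL3A1 at 936.

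At 100 µM, genes of the integrated stress response, the programme driven by the transcription factor ATF4, rose together. CHAC1, which encodes a glutathione-degrading enzyme, rose from 3.56 ± 0.27 to 26.3 ± 0.33 CPM (SD, n = 3 each; log2 fold change 2.88, SE 0.09, edgeR quasi-likelihood adjusted p = 7.1e-22). ADM2, which encodes a peptide hormone of the adrenomedullin family, rose by 2.24 on the log2 scale, ATF3 by 1.77, INHBE by 1.71, and SESN2 and the asparagine synthetase gene ASNS by 1.43 each. STC2 rose from 44.2 ± 0.61 to 99.9 ± 2.2 CPM, DDIT3 by 1.01 and GDF15 by 0.95 on the log2 scale. Of the 23 members of the ATF4 list, 21 rose, 0 fell and 2 were not called over all genes tested, and 22 rose when adjusted over the list alone. The median log2 fold change was 0.70, and camera, which compares a list with all other genes, gave an adjusted p of 1.06e-145 with the preset correlation and an adjusted p of 2.25e-08 with an estimated correlation. CHAC1 lies on chromosome 15 from 40952962 to 40956519, ATF3 on chromosome 1 from 212565334 to 212620777 and STC2 on chromosome 5 from 173314713 to 173329503 (GRCh38). DDIT3 overlaps AC022506.1 on its own strand and MARS on the other, and ASNS overlaps AC079781.5 on its own strand and AC005326.1 on the other. Overlap on the other strand makes counts uncertain where counting did not use strand, which was not given in the sources used here, and overlap on the same strand makes them uncertain with or without it.

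Altogether 1390 of 16196 genes differed from control at 100 µM (edgeR, adjusted p under 0.05), 610 higher and 780 lower, with a median absolute log2 fold change of 0.224. Changes of 2-fold or more were found for 59 genes, 42 higher and 17 lower. Other risers were TRIB3 (log2 fold change 0.80, SE 0.05), an ATF4 target pseudokinase gene, GPT2 (0.70, SE 0.05), a mitochondrial transaminase gene, and DDR2 (1.05, SE 0.15), a collagen receptor gene. TNFSF15, a cytokine gene of the TNF family, fell from 6.51 ± 0.29 to 2.76 ± 0.27 CPM (log2 fold change -1.24, SE 0.12, adjusted p = 6.3e-09). The epithelial transcription factor gene ELF3 fell by 0.83 on the log2 scale, SAMD9 by 1.00, TNS4 by 0.73, C11orf86 by 0.72, ITGB6, an integrin gene, by 0.71, and the phosphatase gene DUSP5 by 0.66. ELF3 overlaps AL691482.3 on its own strand and ELF3-AS1 on the other, ITGB6 overlaps AC092153.1 on its own strand, and WNT5A overlaps WNT5A-AS1 on the other. WNT5A, a secreted signalling ligand gene on chromosome 3 from 55465715 to 55490539, fell from 147 ± 2.3 to 90.9 ± 2.7 CPM. SERF1B (1.53), which has a near-identical copy, the signal recognition particle RNA gene RN7SL2 (-1.11) and the processed pseudogenes HSPE1P2 (-0.91) and RPS7P10 (-0.81) also met the threshold and are uncertain, since reads can be shared with their copies. The call of SERF1B ended when any 1 of the 6 libraries compared was left out, and that of RN7SL2 when any but control replicate 2 was. ITGB6 was not called without control replicate 2 or the 100 µM replicates 1 or 2, HSPE1P2 without control replicate 1 or the 100 µM replicate 2, and RPS7P10 without control replicate 1 or the 100 µM replicate 1. The count of calls was 798 without control replicate 1, 774 without control replicate 2, 699 without the 100 µM replicate 1 and 896 without the 100 µM replicate 3.

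**Figure D2:**
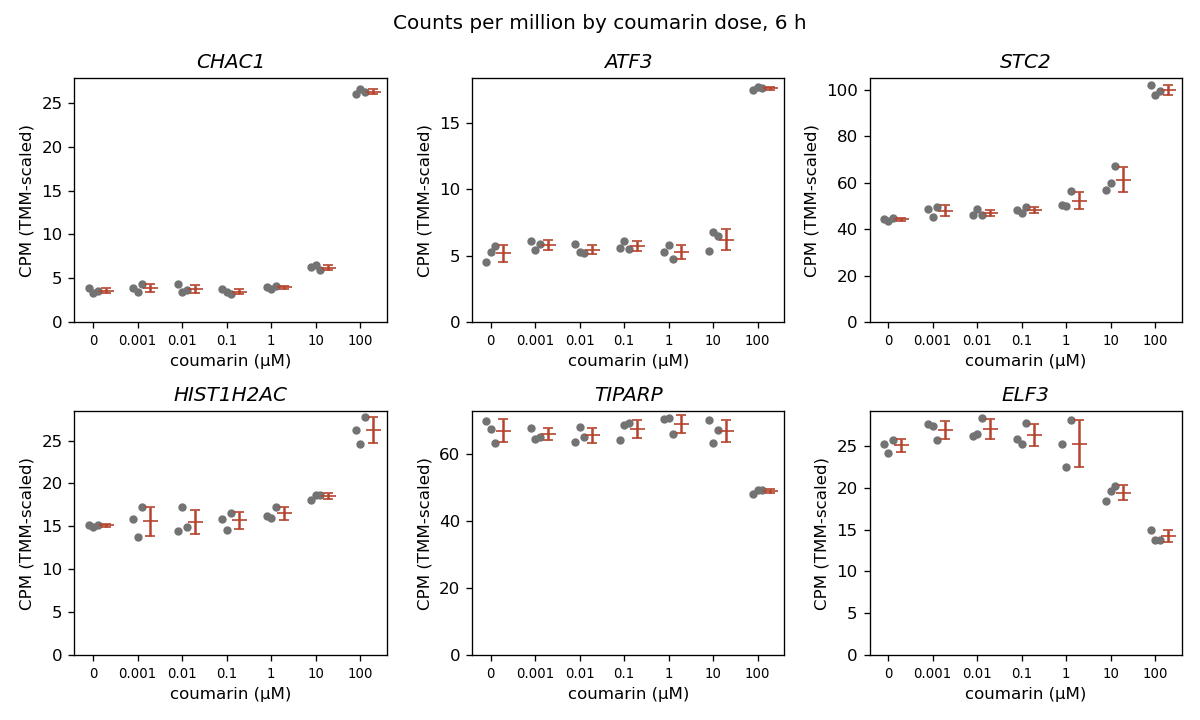
CPM scaled by TMM against coumarin dose for 6 genes, with grey points for the 3 libraries of each dose and red bars for the mean and SD. CHAC1 stood at 3.56 in the control, 6.18 at 10 µM and 26.3 at 100 µM, and ELF3 at 25.1, 19.4 and 14.2.

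Histone genes of the replication-dependent clusters, whose transcripts mostly lack a poly(A) tail, were higher at 100 µM. Of 16 measured members, 9 rose, 0 fell and 7 were not called, and 11 rose when adjusted over the list alone. HIST1H2AC rose from 15.1 ± 0.15 to 26.2 ± 1.5 CPM, HIST2H2BE by 0.99, HIST1H2AG by 0.69 and HIST1H2BK by 0.45 on the log2 scale. The list's median was 0.65, with a camera adjusted p of 1.92e-17 and an adjusted p of 0.000117 with an estimated correlation. Genes of the same histone type, such as H2A or H2B, have near-identical copies, and single members are uncertain for that reason.

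Targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, were mostly lower at 100 µM. Of 10 measured members, 6 fell, 1 rose and 3 were not called, with 7 falling and 1 rising when adjusted over the list alone. TIPARP fell from 66.9 ± 3.4 to 48.9 ± 0.73 CPM, ALDH1A3 and TNFAIP2 each had a log2 fold change of -0.37, and AHRR had -0.32. AHRR shares its strand and position with PDCD6. CYP1A1, the best known target, stood at 0.769 ± 0.26 CPM in the control and 0.419 ± 0.17 at 100 µM (adjusted p = 0.12) and was not called. The camera adjusted p was 3.62e-07, and the adjusted p was 0.00205 with an estimated correlation.

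Of the 9 genes measured on the gluconeogenesis and insulin response list, 3 rose, 1 fell and 5 were not called, with 5 rising and 1 falling when adjusted over the list alone (camera adjusted p = 7.16e-05; adjusted p = 0.0142 with an estimated correlation). The risers were PCK2 (log2 fold change 0.87, SE 0.05), which encodes the mitochondrial phosphoenolpyruvate carboxykinase and overlaps NRL on the other strand, FOXO3 (0.37, SE 0.05) and IRS2 (0.23, SE 0.05). IGFBP1 fell (-0.63, SE 0.17). IRS2 was not called without the 100 µM replicate 1, nor IGFBP1 without control replicate 3 or the 100 µM replicates 2 or 3. The genes PCK1 and G6PC1 of liver glucose output were not tested.

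For 5 other lists, camera made a call at 100 µM that was lost with an estimated correlation. Of 19 p53 targets, 5 rose and 0 fell, with 5 rising when adjusted over the list alone, among them CDKN1A (0.43, SE 0.07) and GADD45A (0.34, SE 0.05); the adjusted p was 0.0926 with an estimated correlation, and the list's trend over dose is given below. Of 21 immediate early genes, 4 rose and 2 fell (6 and 3 when adjusted over the list alone), with JUN at 0.71, KLF4 at 0.78 and IER3 at -0.50; the adjusted p was 0.508 with an estimated correlation. Of 18 heat shock genes, 8 fell and 1 rose (14 and 1 when adjusted over the list alone), with HSPA8 at -0.32 and DNAJA1 at -0.20; the adjusted p was 0.177 with an estimated correlation. Of 28 genes of G2/M and mitosis, 7 fell and 0 rose (13 and 1 when adjusted over the list alone), with ECT2 at -0.25 and CCNA2 at -0.18; the adjusted p was 0.398 with an estimated correlation. Of 9 noncoding RNAs, 4 rose and 0 fell (5 and 0 when adjusted over the list alone), with ZFAS1 at 0.44 and GAS5 at 0.28; the adjusted p was 0.363 with an estimated correlation.

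The remaining 24 of the 33 lists tested were not called at 100 µM. Among 22 targets of the oxidant-sensing factor NRF2, 1 rose and 2 fell (2 and 3 when adjusted over the list alone), with SRXN1 at 0.42 (SE 0.09), TXNRD1 at -0.17 (SE 0.04) and NQO1 at -0.13 (SE 0.04), and the camera adjusted p was 0.994. NQO1 was not called without control replicate 1 or any of the 100 µM libraries, or with limma. HMOX1 had a log2 fold change of 0.12 (SE 0.06, adjusted p = 0.22). Of 7 measured enzymes that act on coumarin, 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.637). Of 19 chaperones and other genes of the unfolded protein response, 2 rose and 3 fell (2 and 6 when adjusted over the list alone), with XBP1 at 0.19 and HSPA5, the main chaperone of the endoplasmic reticulum, at -0.15; the camera adjusted p was 0.201. Among apoptosis regulators, 3 of 21 rose and 2 fell (3 and 3 when adjusted over the list alone), with PMAIP1 at 0.87 (SE 0.07) and BCL2L1 at -0.23 (SE 0.06), and the camera adjusted p was 0.96. Of 11 mesenchymal marker genes, 3 fell and 0 rose (3 and 1 when adjusted over the list alone), with PDGFRB at -0.27 and FAP at -0.51; the camera adjusted p was 0.589.

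Other genes named from the lists also overlap annotated genes, and their counts are uncertain: TIPARP, NQO1, IER3, CDKN1A, IRS2, FOXO3, BCL2L1, FAP, CCNA2, ECT2 and GAS5 overlap genes on the other strand, SRXN1, HSPA8, DDR2 and GDF15 genes on the same strand, and ALDH1A3, TXNRD1, COL3A1 and ZFAS1 genes on both.

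**Figure D3:**
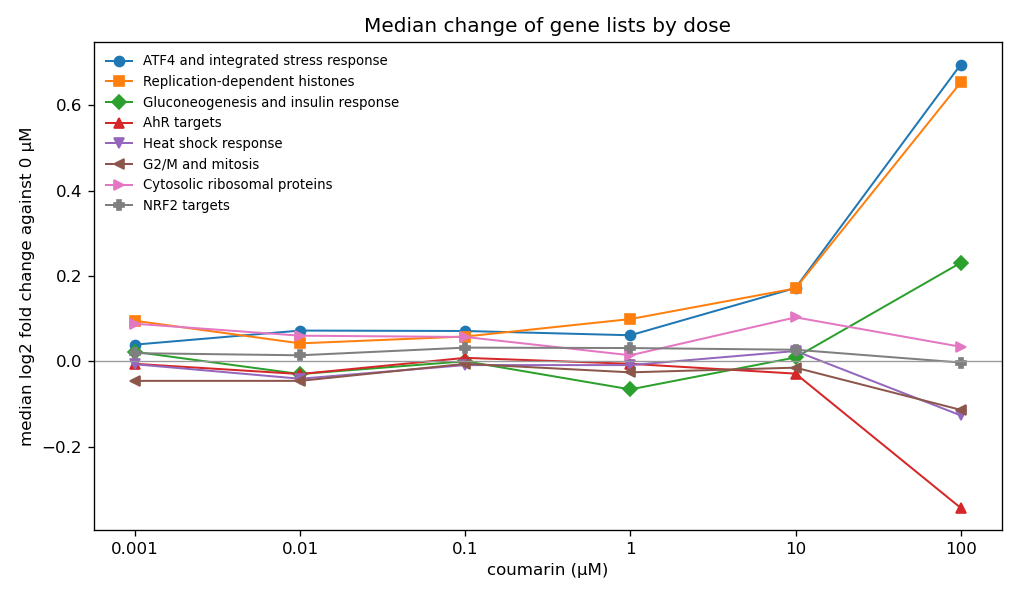
Median log2 fold change against the control for 8 gene lists at each coumarin dose (µM), 1 line per list. The ATF4 list stands at 0.17 at 10 µM and 0.70 at 100 µM, the histone list at 0.17 and 0.65, and the list of aryl hydrocarbon receptor targets at -0.03 and -0.34.

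At 10 µM, 52 genes differed from control, 39 higher and 13 lower (edgeR, adjusted p under 0.05), none by 2-fold or more. CHAC1 rose from 3.56 ± 0.27 to 6.18 ± 0.28 CPM (log2 fold change 0.79, SE 0.10, adjusted p = 8.3e-05), ADM2 rose by 0.67 and STC2 by 0.47 on the log2 scale. C1QL1, which encodes a secreted complement-like protein, stood at 6.93 ± 0.46 CPM in the control and 10.3 ± 0.63 at 10 µM, with 8.97 at 0.001 µM and 8.26 at 100 µM. HIST1H2BD and TMEM256 each had a log2 fold change of 0.48, and GABARAP, an autophagy gene that overlaps AC120057.2 and AC120057.3, had 0.72. The mitochondrial transfer RNA gene MT-TS2 fell most (-0.74, SE 0.14), and RNF207 (-0.46) and DAGLA (-0.38) also fell; of the genes named for 10 µM, MT-TS2, DAGLA, C1QL1 and EGFR-AS1 were not called at 100 µM (adjusted p = 0.12, 0.086, 0.15 and 0.56). WNT5A (-0.24), ELF3 (-0.37), the retinal reductase gene DHRS3 (-0.36), VSIR (-0.34), RASL11A (-0.31) and ZBED5 (-0.25) fell. RPL12P4 (0.86), AC012085.1 (0.48) and RPL21P75 (0.46) are processed pseudogenes, and EGFR-AS1 (-0.59) lies on the strand opposite EGFR, so these calls are uncertain. RNF207, DAGLA, DHRS3, VSIR, ZBED5, HIST1H2BD and TMEM256 also overlap annotated genes. Of the 23 ATF4 list members, 2 rose over all genes and 17 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 3.27e-21; adjusted p = 0.00148 with an estimated correlation). Camera also called the lists of glycolysis and hypoxia genes, cytosolic ribosomal proteins, nuclear respiratory chain subunits, cholesterol synthesis and histones as higher, and with an estimated correlation their adjusted p values were 0.256, 0.457, 0.399, 0.204 and 0.111. Those lists held 0, 1, 2, 0 and 2 risers over all genes, 15, 17, 10, 1 and 5 when adjusted over the list alone, where 1 ribosomal gene fell. These calls were not particular to 10 µM: camera also called each of these lists as higher at 2 or more of the lower doses, with a ribosomal median of 0.088 at 0.001 µM against 0.103 at 10 µM and a respiratory chain median of 0.068 against 0.074. CHAC1, STC2, ELF3 and DHRS3 kept their calls with each library left out in turn, while the other genes named for 10 µM lost theirs without the 10 µM replicate 3. The count fell to 9 without control replicate 2 and to 7 without the 10 µM replicate 3, and with offsets for gene length and GC content it was 96, 53 higher and 43 lower; DESeq2 gave 155, 98 higher and 57 lower. With no filter on low counts it was 302, 224 higher and 78 lower, and limma on the FPKM values gave 25, with 22 of the 52 calls kept. Control replicate 2 had the steepest rise of counts with gene length (0.0495 log2 units per doubling), and the genes raised at 10 µM had a median length of 2058 bases, against 5128 for those lowered and 4233 for all genes tested.

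At 0.001, 0.01, 0.1 and 1 µM, edgeR called 0 genes at each dose. At an unadjusted p under 0.05, 1330, 1415, 987 and 609 genes were found, where 810 are expected by chance. DESeq2 called 0, 1, 1 and 1 gene at these doses, and limma on the FPKM values called 0, 2, 1 and 0. With no filter on low counts the numbers were 10, 20, 5 and 2, and with offsets for gene length and GC content 0, 4, 5 and 2. In the ATF4 list the median log2 fold change stayed between 0.04 and 0.07, and CHAC1 and ATF3 were not called. Camera made 27 list calls over these 4 doses, of which 0 held with an estimated correlation (lowest adjusted p = 0.0852), with 0 members called over all genes, 5 rising and 6 falling when adjusted over the list alone, and a largest absolute median of 0.108. On simulated counts for the 100 µM comparison, the same test recovered 64% of genes changed by 0.322 on the log2 scale and 92% of those changed by 0.585, so smaller changes at the low doses were not excluded. The changed genes there all had a mean log2 CPM above 1, and recovery was not measured for genes with lower counts.

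Across the 7 groups, 753 genes differed (edgeR F-test, adjusted p under 0.05), led by CHAC1, STC2, ATF3, SESN2, ADM2, PCK2, TRIB3, WNT5A, INHBE and GPT2. Among the 6 treated doses alone, without the control libraries in the contrast, 717 genes differed, of which 580 were also called at 100 µM. The slope over log10 dose among treated libraries was called for 721 genes, 313 rising and 408 falling, and 471 of them were called in the same direction at 100 µM. The fitted slope was 0.46 log2 units per 10-fold step of dose for CHAC1 (SE 0.02), 0.34 for ADM2, 0.27 for INHBE and 0.26 for ASNS, and -0.21 for TNFSF15, -0.175 for ELF3, -0.13 for DHRS3 and -0.13 for VSIR. For CHAC1 and ASNS the steps were uneven, and the highest doses carried the slope. CHAC1 stood at 3.88, 3.79, 3.45 and 3.95 CPM from 0.001 to 1 µM and at 6.18 and 26.3 at 10 and 100 µM. ASNS stood at 1.91 to 2.51 CPM from 0.001 to 10 µM and at 5.7 at 100 µM. Of 33 lists, camera called 12 for slope, and 5 held with an estimated correlation, namely the ATF4 list (21 of 23 rose, 22 when adjusted over the list alone; adjusted p = 2.19e-09 with an estimated correlation), histones (8 of 16 rose, 9 over the list alone; 0.000125), aryl hydrocarbon receptor targets (5 of 10 fell and 1 rose, 6 and 1 over the list alone; 0.000503), gluconeogenesis and insulin response (3 of 9 rose, 3 over the list alone; 0.000662) and p53 targets (4 of 19 rose and 0 fell, 4 and 0 over the list alone; 0.00838). The 7-group count was 1415 with no filter on low counts, 1302 with offsets for gene length and GC content, 1139 with DESeq2 and 512 with limma on the FPKM values. The treated-dose count was 1155, 1284, 1004 and 513 with these, and the slope count 729, 1248, 775 and 545. With 1 library left out, the 7-group count was 1144 without the 0.1 µM replicate 1, and 361, 402 and 391 without the 100 µM replicates 1, 2 and 3. The treated-dose count was 354, 371 and 368 without those same 3 libraries, and the slope count was 472 without the 0.001 µM replicate 2 and 461 without the 100 µM replicate 2.

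The 6 comparisons share the 3 control libraries, so their chance values are shared too. Of the 52 genes called at 10 µM, 39 were called in the same direction at 100 µM, 29 higher and 10 lower, where independent lists would share 1.47 and 0.626. With shared controls the 2 lists are not independent. In the simulations described next, the highest number of genes called the same way at both doses was 0. No group was changed there, so only false calls could overlap, and this 0 is no reference for the 39. Over all genes tested, 67.7% had the same sign at both doses, against 66.8% in 20 simulations of unchanged groups. These drew all 21 libraries anew, gene by gene, so the doses shared simulated controls and not the real ones. Traits of the real controls, such as the length trend of control replicate 2, were therefore not carried into the simulated values. The covariance of log2 fold changes between 10 and 100 µM was 0.0278, against 0.0191 in the simulations, and the correlation across genes, which are not independent replicates, was 0.489 against 0.505. Every other pair of doses also had a covariance above its simulated value, such as 0.0248 against 0.019 for 0.1 and 10 µM. An excess was therefore not particular to 10 and 100 µM, though it was largest there. Part of the excess may come from the shared controls, since 3 libraries cannot be split into 2 sets of at least 2.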

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

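Offsets for gene length and GC content were chosen after seeing the data; the other settings were fixed before. With no filter on low counts, 10, 20, 5 and 2 genes were called at 0.001, 0.01, 0.1 and 1 µM, 302 at 10 µM, 1415 over the 7 groups and 1155 over the treated doses. With length and GC offsets the counts were 4, 5 and 2 at 0.01, 0.1 and 1 µM, 96 at 10 µM (37 of the 52 calls kept), 1302 over the 7 groups, 1284 over the treated doses and 1248 for the slope. DESeq2 called 1 gene at each of 0.01, 0.1 and 1 µM, 155 at 10 µM and 1139 over the 7 groups. With limma on log2(FPKM + 1) the counts were 2, 1 and 25 at 0.01, 0.1 and 10 µM, and a fit of only the 6 libraries called 2 at 0.1 µM. For these the cause was not tested. A threshold of an absolute log2 fold change of at least 1 left 0 genes at 10 µM and 59 at 100 µM, by its construction. With an estimated correlation, 5 of the 42 list calls against control and 5 of the 12 for the slope remained. Fry made 17 list calls against control, 13 of them among the 42, and 11 for the slope, 10 of them among the 12.

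Leaving out 1 library in turn gave 0 to 1 genes at 1 µM, 7 to 59 at 10 µM, 699 to 1603 at 100 µM, 361 to 1144 over the 7 groups, 354 to 1027 over the treated doses and 461 to 829 for the slope; such fits hold fewer libraries. The 100 µM count stayed within 1.5 times of 1390 under every setting that kept all libraries of the comparison and the threshold, from 1203 with limma to 1637 with the offsets. The genes called were not all the same. Of the 1390 calls, 1087 were kept in the same direction with the offsets, 1103 with limma, 1175 with no filter on low counts and 1372 with DESeq2 size factors. Among the named genes and lists no direction reversed. Of 1604 alternatives for named genes, 1483 gave the main fit's verdict, called or not called, and 121 lost a call. Genes not called in the main fit, such as CYP1A1 and HMOX1, are among them, and alternatives without an adjusted p were left out. Many of these genes were picked for large changes in the same libraries, so the share does not describe calls in general. Of 165 alternatives for lists called at 10 and 100 µM, 150 kept the call and 15 lost it. Most of these were refits of shared libraries at the preset correlation, so the share kept does not describe separate tests. With an estimated correlation, 1 of 6 lists held at 10 µM and 4 of 9 at 100 µM. Replicate numbers did not pair the libraries (correlations of deviations -0.095 to 0.075 over 63 pairs with the same number, 0 over 0.1; 8 of 21 libraries correlated best with their own number), and with the number as a block the counts were 70 at 10 µM, 1350 at 100 µM, 720, 669 and 699 for the 7 groups, treated doses and slope, 44 and 12 for lists, and 0 at each lower dose. Depth limits low genes: 3 counts correspond to up to 0.107 CPM.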

Other observations

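Tests chosen only after their result was seen were those of the untreated level of hepatocyte genes, of the 6 h in serum-free medium, of the levels of other cell type genes, of the G1/S list and of the size of the change at 10 µM without 1 library; the lists of synthetases, transporters and ERK targets, and PHLDA1 and EMP1, were also picked after the data had been examined, and the counts over the list alone were brought into the verdicts on these lists after both counts had been seen. Genes of amino acid supply moved at 100 µM in part with the ATF4 list. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 8 rose and 0 fell (edgeR, adjusted p under 0.05), or 10 and 2 when adjusted over the list alone, with CARS at 0.60 (SE 0.05), SARS at 0.36 (SE 0.04), GARS at 0.35 (SE 0.04) and AARS at 0.30 (SE 0.04) on the log2 scale, while EPRS (-0.01) and QARS (-0.01) were not called. Of 15 amino acid transporters, 7 rose and 1 fell (8 and 1 when adjusted over the list alone), with SLC6A9 at 0.49, SLC43A1 at 0.45 and SLC1A5 at 0.40, and SLC36A4 at -0.17. Of 17 mitochondrial synthetases, 2 rose (SARS2 at 0.41 and FARS2 at 0.20) and 1 fell (EARS2 at -0.16), or 3 and 4 when adjusted over the list alone.

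The hypothesis was that these groups rise with the ATF4 list as a whole. The 8 cytosolic synthetases and 7 transporters that rose lie between the shares set in advance for and against it over all genes, and the 10 and 8 that rose over the list alone reach the share set for it, so these tests left it open for both groups. The transporters SLC3A2 and SLC7A11 are also members of the ATF4 list. SLC3A2 (0.25) is among the 7 risers, while SLC7A11 (0.18) was not called over all genes. The transporter count is thus not independent of the ATF4 list. The 2 mitochondrial synthetases that rose, 3 over the list alone, argue against it for that group. DUSP5, PHLDA1 and EMP1 fell by 0.66, 0.53 and 0.53 on the log2 scale at 100 µM. Lower feedback signalling of the kinase ERK was a candidate explanation and stays open. Of 14 other feedback targets 2 fell (IER3 at -0.50 and EPHA2 at -0.17), a share below the bound set in advance against it. That bound counted calls over all genes, which small changes miss: adjusted over the list alone 5 fell and 0 rose, a share above it, 12 had a negative change and the median was -0.127.

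Hepatocyte genes were near 0 in all libraries labelled HepG2. A loss of reads in counting that reached over whole regions is argued against by the neighbours of the 18 genes with a mean under 1 read. Of 32 neighbouring protein-coding genes, 46.9% had a mean of at least 10 reads, against 60.5% of all protein-coding genes. Neighbours cannot show a loss confined to the gene itself, which was not tested. Coumarin is argued against by the untreated libraries, where 1 of 24 hepatocyte genes reached 1 CPM, while the 6 h in serum-free medium stays open, since 0 of the 21 libraries were without it. That the cells were not hepatocyte-like may account for the pattern. Of the 14 mesenchymal and 12 biliary and squamous list genes, 6 exceeded 10 CPM, with KRT7 at 1210 and COL3A1 at 936. KRT7 was the only biliary or squamous gene among them, and other genes of both lists were near 0, such as COL1A2, PDGFRA, KRT19 and EPCAM. A different line under this label and a HepG2 culture that had lost these transcripts, before or during those 6 h, were not told apart by any test here.

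The 52 genes called at 10 µM were the second pattern. Offsets for gene length and GC content kept 71.2% of the calls. They turned the length trend and did not remove it: the Spearman correlation of change with length across genes went from -0.13 to 0.09. At 100 µM, without offsets, it was also -0.13. The calls kept thus held under a length trend of either sign. No fit was free of the trend, so a length or GC trend was not excluded. A single library stays open: in the test set in advance, the lowest share of calls kept without 1 of the 6 libraries was 13.5% (7 genes, without the 10 µM replicate 3; 9 without control replicate 2), which met the bound written for that explanation. A second test, chosen after that result, gave a lowest median change of 91.7% of its value with all libraries. It used the genes picked for their change with all 6 libraries, which favours a high share, so it cannot weigh against a single library. A response that continues at 100 µM was not settled, with 48.1% of the genes changed further in the same direction.

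Histone genes were higher at 100 µM. A shift of reads between near-identical copies is argued against by the summed counts of 90 histone genes, which rose by 0.51 on the log2 scale (SE 0.05). For weaker poly(A) selection, 108 genes of non-polyadenylated RNA classes had a median change of 0.016 (95% bootstrap bounds -0.039 and 0.073), against 0.64 for 39 tested histone genes. Genes of these classes can lie within other genes, as small nucleolar RNA genes do within ZFAS1 and HSPA8. Their counts can then come from the surrounding transcripts, so this test cannot decide, and weaker selection stays open. More cells in S phase is argued against by the G1/S and DNA replication list, with a median of -0.032 (95% bootstrap bounds -0.078 and 0); of its 29 members 0 rose and 3 fell over all genes, and 1 rose and 5 fell over the list alone. A change in histone transcripts that carry a poly(A) tail is a hypothesis consistent with these values, found and tested on the same data, and tail length was not measured.

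Other splits of the same libraries were tried. For each dose against control there are 10 splits, too few for a share under 0.05: the real split gave 52 genes at 10 µM and 1390 at 100 µM, with 0 as the highest other at both and 1 of 10 splits as large. At 0.001, 0.01, 0.1 and 1 µM the real split gave 0 genes, all 10 splits gave as many, and the highest others gave 0, 2, 1 and 1. Over the 7 groups 1 of 100 splits, the real one, gave as many as 753 genes (highest other 290). Over the treated doses it was also 1 of 100 (717, highest other 83), and for the slope 1 of 100 (721, highest other 103). A chance assignment of libraries to doses is thus unlikely for these 3 results, though 100 splits cannot show a share below 1 of 100. The 3 results share the 100 µM libraries and are not separate evidence. A departure at 100 µM alone could give each of them, so the slope splits do not show a trend over the lower doses.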
